A study of Xenopus laevis with 12 samples.

How the data were processed

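RNA was measured in 12 libraries from foregut endoderm explants of Xenopus laevis, the African clawed frog. Per the labels, endoderm of the foregut was dissected from wild-type embryos at Nieuwkoop-Faber (NF) stage 15 and kept at 15 °C for about 16 hours, to NF stage 25. Each library came from a pool of 8 explants, which the labels count as 1 biological replicate. There were 4 groups of 3 pools: vehicle (0.1% DMSO) and retinoic acid (RA) at 25, 200 or 500 nM. Per the labels' protocols, libraries were made from mRNA with a kit that keeps the strand. The labels do not say whether the 3 pools of a group came from separate clutches or days, so the p-values measure the spread between these pools.

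The authors deposited a table of expected counts per gene ID, written as whole numbers, and a table of TPM, a measure scaled to transcript length and to 1 fixed total per library, for the same IDs and libraries. Per the submitters' processing notes, RSEM 1.3.0 and Bowtie2 were used. The role and order of these tools, the Bowtie2 version, the genome build and the annotation are not given in the sources used here. RSEM divides reads that match several genes among them, so counts of near-identical copies are estimates. Xenopus laevis carries many genes in a pair of similar copies on its L and S chromosomes, and such copies can share reads. Among IDs with a mean count of at least 10, 32 IDs in 11 sets had identical counts in all libraries, and these held 2.28% to 15.6% of a library's counts. The TPM values deposited by the authors had the same total in each library, within rounding, and carry no depth.

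The tables hold 44479 rows, of which 1 names no gene and has a count of 0. That row was left out. The IDs are not paired with gene names in the tables. A RefSeq gene table of the assembly Xenopus_laevis_v10.1 was searched on all its identifiers, and 0 IDs matched. For this reason the 26 gene lists fixed before the data were examined, and the sums of L and S copies, were not run. The rule for named genes, also fixed then, listed RA-response genes, list members, and the largest rises and falls among genes with a symbol. Without symbols only its last part could be used, without its symbol condition. At 500 nM RA it takes the IDs with the largest log2 fold change against DMSO that had an adjusted p under 0.05, a mean of at least 5 CPM (counts scaled to a fixed library total) in the higher group, and no overlap between the 3 RA and 3 DMSO values. The largest 2 rises and 2 falls are given by ID, and these IDs are not interpreted.

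Total counts were 17782601 to 39147729 per library. The deposited expected counts were already whole, and rounding them changed none. Counts were analysed in R 4.3.3 with edgeR 4.0.16. IDs with low counts were removed with filterByExpr at its minimum count of 10, which left 24454 IDs, and libraries were scaled by TMM factors (0.891 to 1.06). A robust quasi-likelihood model with 4 groups was fitted to all 12 libraries. Each dose was compared with DMSO and with the next lower dose, and a further F-test asked whether an ID differed among the 4 groups. P-values were adjusted by Benjamini-Hochberg over the IDs tested, and an ID was called at an adjusted p under 0.05. Counts of calls with at least a 2-fold change are given as well. Standard errors of log2 fold changes were computed from the fitted model's information and its quasi-likelihood dispersion, with the counting error as the lower bound. The dispersion draws on all groups and on other IDs, so such an error can be smaller than the spread of 1 group. The common biological coefficient of variation was 6.02%. Principal components and Spearman correlations used log2 CPM with a prior count of 2. Replicate pairs were compared by a chi-square test of their counts, and all pairs differed by more than sampling noise (chi-square per degree of freedom 2.90 to 88.3), so each library was counted once.

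The same steps were tested on simulated counts modelled on 25 nM RA against DMSO. Of the 24454 IDs, 50 were changed at each size, and 24056 passed the filter. An adjusted p under 0.05 was reached by 36% of the IDs changed 1.25-fold, 72% of those changed 1.5-fold, 72% of those changed 2-fold and 92% of those changed 4-fold, with 8 false calls. Changed IDs that the filter removed counted as missed. Few IDs were changed here, while 39.96% were called in the real comparison, so the adjustment was stricter in the simulation. These shares therefore do not give the recovery in the data. The true log2 fold change lay within the nominal 95% interval from the standard error for 94.8% of the simulated IDs. Comparisons with DMSO share the same 3 control libraries. The overlap expected from shared controls was therefore simulated with unchanged groups in 10 draws.

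The alternatives fixed before the data were examined were DESeq2 size factors, DESeq2 1.42.0 itself, no filter or a filter of 1 CPM in 3 libraries, a replicate block, a fit of the compared groups alone, limma 3.58.1 on log2(TPM + 1) or log2(TPM + 0.1), and leaving out each replicate in turn. The alternatives added after seeing the data were a fit without 3 libraries that lie towards another group, the first residual component as a covariate, and libraries thinned to equal depth. A set of IDs at least 8-fold higher at 200 than at 25 nM RA, with a mean of at least 3 CPM at 200 nM, was also defined after seeing the data, and several other cutoffs were looked at before this one was chosen. How far a library lay between its own group and another was measured as a median fraction over IDs. These IDs differed at least 1.5-fold between its own group and the other, with mean CPM from 5 to 2000. The 95% bootstrap intervals came from 1000 draws of IDs taken as independent, and they hold no variation between pools. The numerator was the difference of the library from a second library of its group, and the denominator was the difference of the other group's mean from the remaining library of its own group, with which the IDs were chosen. On simulated libraries with a share of 0.25 mixed in, the fractions recovered were 0.232 for a 500 nM library and 0.219 for a 200 nM library. In the data, 500 nM replicates 1 and 3 each served as the other's remaining library. If both were shifted, that distance is too short and their fractions too large, which the simulation did not cover.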

Results

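Gene expression was measured in foregut endoderm, the embryonic tissue layer that gives rise to organs such as lung, liver and pancreas, after culture with retinoic acid. Retinoic acid is a vitamin A derivative that acts through nuclear receptors and patterns the embryo from front to back. The 12 libraries fell into 4 groups of 3 pools, with DMSO vehicle or RA at 25, 200 or 500 nM. Total counts ranged from 17782601 to 39147729 per library, and 29604 to 31104 gene IDs had at least 1 count. The deepest library was 500 nM replicate 1 and the shallowest was DMSO replicate 2. The 50 most counted IDs held 23.6% to 34.9% of the counts, with the highest share in 200 nM replicate 1.

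Libraries of a group resembled each other more than libraries of other groups. Spearman correlations across genes were 0.989 to 0.993 within groups, and genes are not independent replicates. Between groups, the median correlation was 0.970 for DMSO with 25 nM RA, 0.977 for DMSO with 200 nM and 0.966 for DMSO with 500 nM. Among the RA groups it was 0.974 for 25 with 200 nM, 0.984 for 25 with 500 nM and 0.978 for 200 with 500 nM. The first 3 principal components held 41.15%, 18.73% and 10.62% of the variance. The 3 DMSO libraries and the 3 libraries at 25 nM RA each lay close together, while 500 nM replicate 2 and 200 nM replicate 3 lay apart from the other libraries of their groups.

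**Figure D1:**
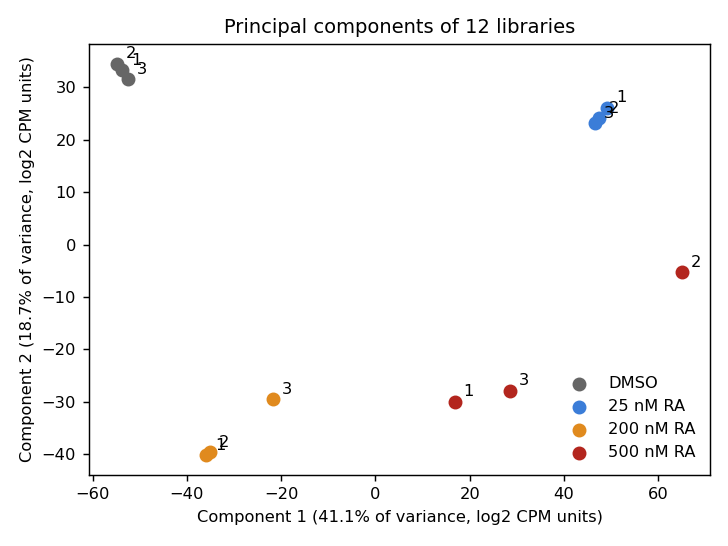
Positions of the 12 libraries on the first and second principal components of log2 CPM, one point per library, coloured by group and numbered by replicate. On component 1 the DMSO libraries lie near the 200 nM libraries and the 25 nM libraries nearer the 500 nM libraries, and 500 nM replicate 2 lies apart from replicates 1 and 3.

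Across the 4 groups, 12965 of the 24454 IDs tested (53.02%) differed in the edgeR F-test at an adjusted p under 0.05. Whether the response followed the dose was asked of these IDs by the order of the group means. The order DMSO, 25, 200, 500 nM, upwards or downwards, was seen for 15.3% of them. The order DMSO, 200, 25, 500 nM was seen for 32.7%, and each order would hold 8.33% if all orders were equally frequent. They were not, since 2431 IDs were called higher and 2195 lower than DMSO at every dose. Orders with DMSO at an end are thus favoured, and 8.33% sets no level for a response that follows the dose. Without 500 nM replicates 1 and 3 and 200 nM replicate 3, the 3 libraries that lay part of the way towards another group, the values were 13.6% and 33.8% of 12142 IDs. That fit leaves 1 library at 500 nM, replicate 2, which is assumed to vary like the other groups, so its counts for 500 nM have no replicates of their own. Replicates 1 and 3 at 500 nM correlated at 0.993 (Spearman), the highest value of all replicate pairs, so replicate 2 may be the displaced library instead. Without replicate 2 alone, 9973 IDs were called at 500 nM against DMSO and 5705 against 200 nM, and the orders were not counted.

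At 25 nM RA, 4797 IDs were higher and 4974 lower than in DMSO. Of these, 816 were at least 2-fold higher and 1143 at least 2-fold lower, against 235 and 263 by limma on log2(TPM + 1). That fit differs in test, unit and filter (19003 IDs), and its scale understates changes of low IDs. The median size of a called change was 0.43 on the log2 scale, and the median standard error over the IDs tested was 0.13. XBXL10_1g32591 rose from 7.50 ± 0.793 CPM in DMSO to 128 ± 5.22 CPM (SD, n = 3 each), a log2 fold change of 4.08 (SE 0.0662). XBXL10_1g30318 fell from 72.3 ± 5.41 CPM to 3.47 ± 0.603 CPM (SD, n = 3 each), a log2 fold change of -4.37 (SE 0.234). The edgeR adjusted p-values of these changes were 3.24e-50 and 1.26e-07, and the changes were seen in all 3 RA libraries. With edgeR fitted to the DMSO and 25 nM libraries alone, the adjusted p-values were 5.12e-93 and 3.22e-76.

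At 200 nM RA, fewer IDs differed from DMSO than at 25 nM. There were 3558 IDs higher and 3157 lower, of which 763 were at least 2-fold higher and 415 at least 2-fold lower. XBXL10_1g32591 reached 152 ± 7.28 CPM (SD, n = 3), a log2 fold change of 4.33 (SE 0.0659). XBXL10_1g30318 stood at 8.16 ± 1.06 CPM (SD, n = 3), a log2 fold change of -3.15 (SE 0.186). The edgeR adjusted p-values were 1.03e-51 and 9.16e-07. By limma on log2(TPM + 1), which differs in test, unit and filter (19003 IDs), 1769 IDs were higher and 2665 lower, while at least 2-fold changes were 181 higher and 122 lower. With DESeq2 size factors in the edgeR test, 3523 were higher and 3227 lower.

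At 500 nM RA, 5459 IDs were higher and 5529 lower than in DMSO. Their number, 10988, was above the 9771 at 25 nM with all libraries. With 500 nM replicate 1, 2 or 3 left out in turn, 10450, 9973 and 9976 were called at 500 nM. Counts at 25 nM were not taken from those fits. Without the 3 libraries only 1 library is left at 500 nM, so its count was not set against that at 25 nM. At least 2-fold changes were 1102 higher and 1165 lower. XBXL10_1g32591 reached 213 ± 1.64 CPM (SD, n = 3), a log2 fold change of 4.81 (SE 0.0655), and XBXL10_1g3046 rose from 0.802 ± 0.251 CPM in DMSO to 19.9 ± 0.534 CPM (SD, n = 3 each), a log2 fold change of 4.65 (SE 0.211). XBXL10_1g30318 fell to 1.16 ± 0.778 CPM (SD, n = 3), a log2 fold change of -5.88 (SE 0.344). It stood at 1.46, 0.278 and 1.75 CPM in replicates 1, 2 and 3 at 500 nM, and without the 3 libraries its log2 fold change was -7.99, from replicate 2 alone with 6 counts. The edgeR adjusted p-values of the changes of XBXL10_1g32591, XBXL10_1g3046 and XBXL10_1g30318 with all libraries were 2.24e-54, 4.32e-32 and 3.18e-08. With edgeR fitted to the DMSO and 500 nM libraries alone, they were 2.18e-39, 9.48e-25 and 6.42e-05. XBXL10_1g26263 had 103 to 126 counts in the DMSO libraries and 1 to 3 counts in the 500 nM libraries, with an edgeR adjusted p of 5.94e-12, and the size of its fall is limited by the low counts. At 500 nM, limma on log2(TPM + 1) gave 3236 IDs higher and 4884 lower, of which 328 and 385 changed at least 2-fold.

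**Figure D2:**
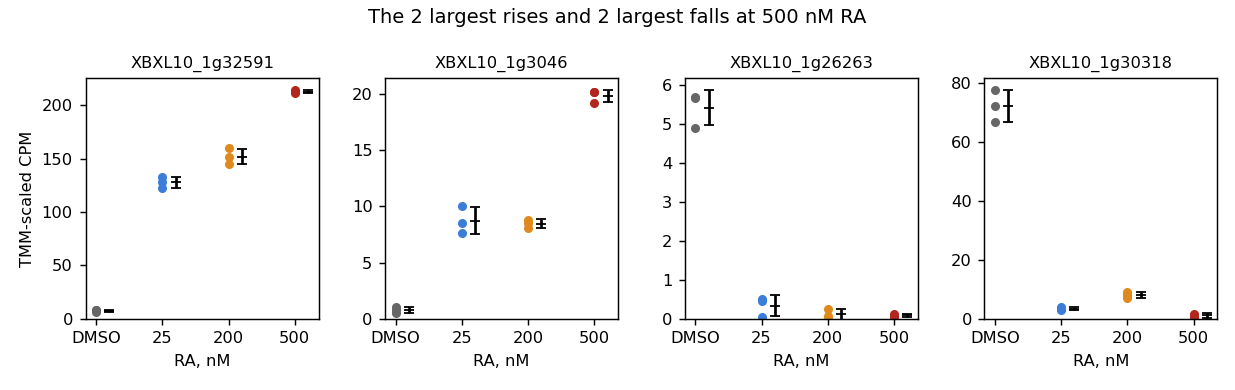
TMM-scaled CPM of the 4 IDs with the largest rises and falls at 500 nM RA by the naming rule, against RA dose. Coloured points are single libraries and the black marks show the mean and SD of 3 libraries. XBXL10_1g32591 lies at 7.50 CPM in DMSO and 213 CPM at 500 nM, and XBXL10_1g30318 at 72.3 and 1.16 CPM.

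The IDs that changed at least 2-fold at 500 nM were followed at the lower doses. Of the 1102 higher IDs, 76.0% were also called higher at 25 nM and 70.7% at 200 nM, with median log2 fold changes of 1.09 at 25 nM, 0.98 at 200 nM and 1.41 at 500 nM. Of the 1165 lower IDs, 77.8% were called lower at 25 nM and 44.9% at 200 nM, where 48 were called higher, with medians of -1.25, -0.60 and -1.64. These sets were chosen by their change at 500 nM, so their size at that dose is partly a result of the choice. The same DMSO libraries entered each of these comparisons.

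Overlaps of calls between doses were set against lists drawn independently. In the same direction, 4995 IDs were shared by 25 and 200 nM, 5336 by 200 and 500 nM, and 7689 by 25 and 500 nM. Independent lists would share 1340, 1508 and 2195 IDs. Unchanged groups simulated against the shared controls shared at most 1, but such groups give few calls, so that value sets no level for lists of this length. The correlation of log2 fold changes across genes was 0.399, 0.646 and 0.707, against 0.517, 0.509 and 0.527 for unchanged groups, so that for 25 and 200 nM it lay under the simulated value. Spearman correlations of the same values were 0.601, 0.621 and 0.759, and no simulated value is given for them. The covariance of log2 fold changes was 0.203, 0.275 and 0.462, against simulated values of 0.046, 0.0445 and 0.0463. The simulated covariance is the part expected from the shared controls, and the differences from it were 0.157, 0.231 and 0.416. The 3 control libraries cannot be split into parts of 2, so this was not checked with separate controls.

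The direct comparison of 200 with 25 nM RA asked whether the higher dose extended the change seen at the lower. At 200 nM, 2504 IDs were higher and 2364 lower than at 25 nM. Among changes of at least 2-fold, 904 were higher at 200 nM and 91 lower, so that 90.85% were higher. Without the 3 libraries named above, the counts were 1030 and 153. By limma on log2(TPM + 1), 712 IDs were higher and 1260 lower, and the at least 2-fold changes were 213 and 17. Of the 3876 IDs higher than DMSO at both 25 and 500 nM, 1286 were nearer to DMSO at 200 than at 25 nM and 116 farther from it, each with an adjusted p under 0.05 in edgeR between 200 and 25 nM. Of the 3813 IDs lower at both, 1159 were nearer and 156 farther. These IDs were chosen by their calls at 25 and 500 nM and not at 200 nM, and the same 25 nM libraries entered the comparison, so the choice itself favours values nearer to DMSO at 200 nM. In opposite directions from DMSO, 223 IDs were lower at 25 and higher at 200 nM, and 33 the reverse. Without the 3 libraries these counts were 365 and 79.

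A set of 126 IDs was at least 8-fold higher at 200 than at 25 nM RA, and 0 IDs met the same condition the other way. The cutoff was chosen after seeing the data. The IDs were chosen by their values in these same 25 and 200 nM libraries. Low levels at 25 nM, high levels at 200 nM and calls in those directions are therefore favoured by the choice. Of the set, 124 were called lower at 25 nM than in DMSO, 50 higher at 200 nM than in DMSO, and 65 lower at 500 nM than in DMSO. As a percentage of the mean of the 200 nM group, the median level was 47.5% to 49.6% in the DMSO libraries and 2.14% to 2.26% in the 25 nM libraries. In the 200 nM group it was 113%, 112% and 76.2% in replicates 1, 2 and 3. In the 500 nM group it was 28.9%, 1.99% and 19.7%, so that the libraries of that group did not share a level.

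**Figure D3:**
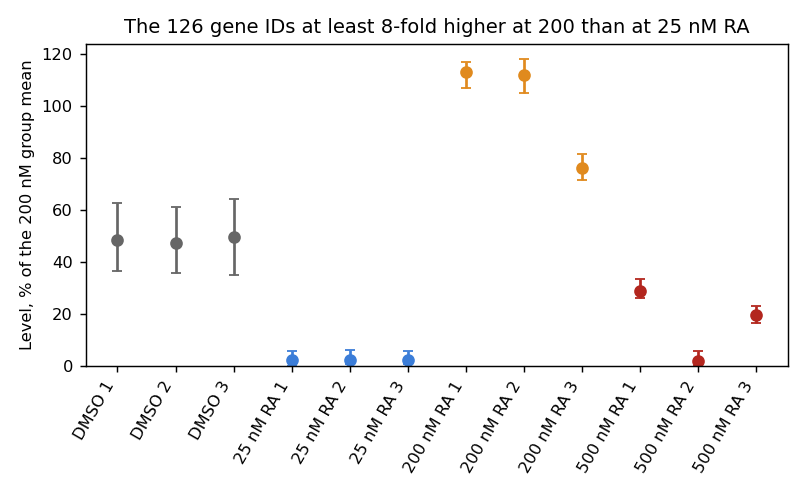
Level of the 126 IDs in each library, as a percentage of the mean of the 200 nM group. Points are medians over the IDs and bars span the quartiles. The 3 libraries at 25 nM lie at 2.14% to 2.26%, and the 500 nM libraries at 28.9%, 1.99% and 19.7%. The IDs were chosen by their 25 and 200 nM values.

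Between 500 and 200 nM RA, 3423 IDs were higher and 3691 lower at 500 nM. At least 2-fold changes were 256 higher and 966 lower. By limma on log2(TPM + 1), 1746 IDs were higher and 2276 lower, of which 34 and 244 changed at least 2-fold. XBXL10_1g3046 rose further between these doses, by 1.23 on the log2 scale (SE 0.103), and XBXL10_1g30318 changed by -2.73 (SE 0.363), with edgeR adjusted p-values of 2.26e-14 and 0.000166. Without the 3 libraries named above, at least 2-fold changes were 338 higher and 1114 lower, from 1 library at 500 nM, with the spread taken from the other groups. Of the 126 IDs, 118 were called lower at 500 than at 200 nM, which their choice as high at 200 nM favours. The median levels of all 126 differed among the 3 libraries at 500 nM, as given above.

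**Figure D4:**
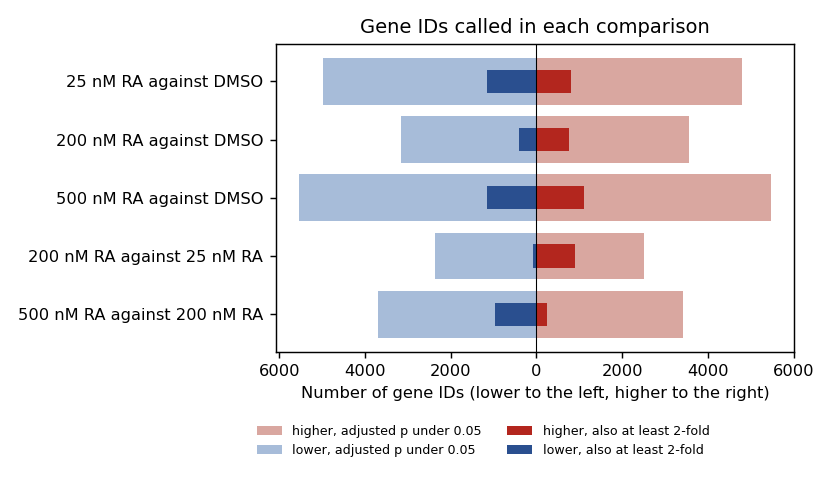
Number of IDs called in each comparison by edgeR, with lower to the left and higher to the right. Wide bars show all calls and narrow bars those with at least a 2-fold change, for example 904 higher and 91 lower at 200 against 25 nM.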

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

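The fit without 3 libraries, the residual component and the thinning to equal depth were chosen after seeing the data; the other alternatives were fixed before. Requiring a 2-fold change left 1959, 1178 and 2267 IDs at 25, 200 and 500 nM against DMSO, 995 at 200 against 25 nM and 1222 at 500 against 200 nM. Limma on log2(TPM + 1) gave 6505 at 25 nM, 4434 at 200 nM, 1972 at 200 against 25 nM, 4022 at 500 against 200 nM and 8359 over the groups. With log2(TPM + 0.1) these were 6464, 4358, 1932, 4001 and 8339. Without its filter, log2(TPM + 1) gave 2233 at 200 against 25 nM and 4058 at 500 against 200 nM. The cause of the lower counts was not tested. The other 105 alternative counts were within 1.5 times the counts reported, and all 216 alternative values of the 4 IDs kept direction and side of the threshold. Without the 3 libraries the counts were 10100 at 25 nM, 6308 at 200 nM and 5362 at 200 against 25 nM. This leaves 1 library at 500 nM, assumed to vary like the other groups. That fit does not check the 500 nM results against their own spread, so its counts that use 500 nM are not given here. With 500 nM replicate 1, 2 or 3 left out in turn, 10450, 9973 and 9976 IDs were called at 500 nM against DMSO. In the order of comparisons used above with the F-test last, DESeq2 gave 8376, 5476, 9728, 3833, 5711 and 11180. Thinned to the total count of the shallowest library, the counts were 9087, 6260, 10475, 4223, 6375 and 12004. How recovery of simulated changes depends on depth was not tested. Gene lists and summed L and S copies were not run, since no ID could be given a symbol.

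With a replicate block the counts were 9701, 6700, 10967, 4839, 7079 and 12808. Deviations of same-numbered libraries correlated at -0.0535 to 0.107 over 18 pairs, 1 of them over 0.1. The mean was 0.00486 for the same number and -0.00239 for other numbers. Of 12 libraries, 7 correlated best with their own number, and whether this exceeds random matches was not tested. These values are small and do not decide on pairing. The numbers were not taken to pair the samples, because the labels do not say that they do.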

Other observations

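The tests of mixing, of an extra tissue, of exchanged labels and of a missing tissue were chosen after the result was seen, as were the ratios of spread over better counted IDs; the whole-set spread test, the splits and the test at equal depth were set before their results were seen, though the interval of the spread test and the thinning to equal depth were added after seeing the data. Other splits of the 6 libraries of a comparison are too few, at 10, for a share under 0.05. Fitted to those libraries alone, the real split gave 9714, 6968, 10588, 5051 and 6806 IDs, and the highest of the others gave 0, 0, 0, 1 and 0, with 1 of 10 splits as large as the real one each time. Over the 4 groups, 1 of 100 splits gave as many as the real 12965 IDs, the highest other gave 8870, and chance can be excluded for that count.

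A group of 3 libraries lay part of the way towards another group, each measured against a second library of its own group. The fraction changes sign when those libraries are exchanged, so it does not tell which of them was displaced. On the first residual component, 500 nM replicate 2 loaded at 0.784, and replicates 1 and 3 at -0.464 and -0.32. Replicate 2 may thus be the odd library at 500 nM. At 200 nM, replicate 3 was shifted towards 25 nM from replicate 2 as well, by 0.279. Compared with 500 nM replicate 2, replicates 1 and 3 were shifted towards the 200 nM group by fractions of 0.27 (95% interval 0.247 to 0.288) and 0.191 (0.163 to 0.208) of the distance from the group's remaining library, and 200 nM replicate 3 was shifted from replicate 1 towards the 25 nM group by 0.294 (0.271 to 0.32); shifts towards further groups were smaller but also above those of the DMSO and 25 nM libraries, at 0.155 towards 25 nM and 0.116 towards DMSO for 500 nM replicate 1, 0.0913 and 0.0595 for replicate 3, and 0.123 towards 500 nM for 200 nM replicate 3, whose 0.0228 towards DMSO (0.00576 to 0.0311) was not clear of them, while 36 fractions in DMSO and 25 nM libraries, which come in mirrored pairs, lay between -0.0084 and 0.0084 over both directions together and between -0.0496 and 0.0496 for either direction alone. The fractions of 500 nM replicates 1 and 3 may be too large, since each served as the other's remaining library. The intervals resample IDs and hold no variation between pools, so they may be too narrow. IDs higher and lower in the other group moved alike, with a smallest fraction of 0.155. This argues against 1 extra tissue that would move only IDs higher in the other group. A different share of tissues in the pool could move IDs both ways and was not tested. RNA or reads of another group in these libraries could also give such fractions, without showing that a single group was the source. RNA, reads and explants were not told apart. A lower effective exposure to RA stays open for the 500 nM libraries. The test set beforehand compared the spread of the log2 ratio to a 200 nM library with that in a thinned 200 nM replicate. Over the 126 IDs the spread was 2.12 times as large for replicate 1 and 2.08 times for replicate 3. Both values lay above the bound of 1.5, the side set for a lower exposure. Their intervals, added after seeing the data, reached under that bound (1.49 to 2.86 and 1.47 to 2.73). Over IDs nearly off in 500 nM replicate 2 with 50 counts expected, the ratios were 1.09 (62 IDs) and 1.32 (17 IDs). This restriction was made after that test was set. For 200 nM replicate 3 the ratio was 1.06 over 90 IDs nearly off at 25 nM with 50 counts expected, and 0.98 over the 126. Both lay under the bound. The bound was assumed, and the spread that a lower exposure would give was not simulated. These ratios therefore do not decide on a graded lower exposure there.

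The 25 nM libraries lay farther from DMSO than the 200 nM libraries did. With every library thinned to the same total count, 9087 IDs were called at 25 nM and 6260 at 200 nM, a ratio of 1.45, which argues against total depth as the cause, though the spread of counts over IDs was not matched (TMM factors 0.891 to 1.03 in these 6 libraries). An exchange of the labels of these groups may give the order DMSO, 200, 25, 500 nM, which 32.7% of the differing IDs showed against 15.3% in the labelled order, and a tissue present in the DMSO and 200 nM pools and missing from the 25 nM pools could give the 90.85% of at least 2-fold differences that were higher at 200 nM. The 4 named IDs do not decide on an exchange: from 25 to 200 nM, XBXL10_1g32591 changed by 0.25 on the log2 scale (edgeR adjusted p 3.13e-06), in the labelled order, and XBXL10_1g30318 by 1.22 (0.00903), in the exchanged order, while XBXL10_1g3046 at -0.05 (0.824) and XBXL10_1g26263 at -1.52 (0.112) were not called. Neither explanation can be told apart from a response to RA that does not follow the dose, which was not tested. The reason is that no ID could be given a symbol and the makeup of the pools goes with the groups.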
